A study of Deinococcus metallilatus with 2 samples.

How the data were processed

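RNA sequencing libraries came from 2 strains of Deinococcus metallilatus MA1002, the wild type and UV mutant No. 6, with 1 library per strain. Per the labels' protocols, both strains were grown with shaking in TYG medium for 24 h, a point the labels call the exponential phase, total RNA was isolated on RNeasy columns and libraries were made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, Bowtie2 was used, with no version given. The genome build, the read counter, its strand setting and its treatment of reads that match several genes are not given in the sources used here.

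The deposited table holds whole-number read counts per annotated row, not normalised by the authors, together with the contig, position, strand and annotation text of each row. Both count columns were matched to their samples by the sample names in the labels. The table lists 4264 rows on 3 contigs, which it numbers 1, 2 and 3, and positions are given as the table gives them. Of these rows, 61 are stable RNAs, 12 ribosomal RNAs and 49 transfer RNAs, and they hold 0 reads in both libraries, so they were left out and 4203 genes were analysed. The lengths of all of these genes are multiples of 3, so the rows cover coding sequence without untranslated parts. No reference genome was used. Product names come from the table's own text, are based on similarity to proteins of other organisms, and were absent or uninformative (hypothetical or uncharacterized) for 1681 genes. Among neighbouring genes, 899 pairs overlap, 52 of them on opposite strands. Counts of genes with a close copy elsewhere, such as transposases, and of overlapping genes are uncertain for this reason.

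The counts summed to 30493865 in the wild type library and to 18432802 in the mutant library. The median gene had 890 reads in the former and 493 in the latter. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 on the library totals. The log2 ratio of a gene is that of its scaled count in the mutant library over the wild type library, with no prior count. A count of 0 was set to a floor of 3 reads, which makes the ratio a bound. A 95% interval was computed for each ratio by the exact Clopper-Pearson method, conditional on the gene's total over both libraries. Reads were not counted by molecular identifier, so these intervals and floors cover counting error only, and they leave out variation between cultures. A 95% interval of a median over genes was read from the ranked ratios of these genes with binomial limits. It treats neighbouring genes as independent draws, which can make it too narrow, and it too leaves out variation between cultures.

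With 1 library per group there are no residual degrees of freedom, so no test was made and no p-value is given. Genes were called by size alone, as higher or lower in the mutant library by 2-fold or more with at least 50 reads in the library where they were higher. A total of 4092 genes passed this minimum. For 31 gene lists, matched on product names by fixed patterns, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. The percentile of the median among them describes these libraries and is not a test. Random lists draw genes singly, so a list made largely of neighbouring genes that vary together can have too extreme a percentile. Lists were searched in protein names and not in the free text that describes functions. That choice was made after the table had been opened and before ratios were computed, and the whole text was tried as an alternative.

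Named genes follow a rule fixed before the data were examined. It takes the 15 largest and the 15 smallest log2 ratios among genes with at least 100 reads in the higher library, the 10 most abundant genes of each library, all members of the carotenoid list, up to 2 members with the highest and 2 with the lowest ratio of each other list, and the 4 longest runs per direction of at least 3 neighbouring called genes on the same strand. Genes named outside this rule are said to have been chosen after their values were seen. The depleted block of contig 1 was defined after the data were examined. It spans the longest stretch of genes with at least 50 wild type reads and a ratio under 1/16, bridging at most 3 other genes at a time.

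The ratio, interval and list calculations were tested on simulated data, with Poisson counts drawn for the 4203 genes from the wild type proportions at the library sizes of this comparison and 200 genes shifted. All 100 genes shifted by 1.5 on the log2 scale and all 100 shifted by 3.0 were called in the right direction, and 0 of 3854 unshifted genes past the minimum were called. The intervals held the true value for 95.3% of genes. Of 20 random lists of unshifted genes, 1 lay outside the central 95% of its matched lists, and a list of 20 shifted genes had a percentile of 100. The simulation holds no variation between cultures. Its shifted genes were drawn singly, as many up as down, so it does not test the scaling under a change of a whole region such as contig 1.

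Alternatives planned before the data were examined were scaling by library totals, by DESeq2 1.42.0 size factors, by upper quartile factors and by totals without the 10 most abundant genes, prior counts of 0.5 and 5 reads, read minimums of 0, 10 and 200, thresholds of 1.5-fold and 4-fold, and calls by the whole counting interval. Those added afterwards were TMM factors from contig 3 alone, counts without contig 1 and the whole annotation text. The deposited table gave counts alone, so the planned comparison with normalised values was not run. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.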

Results

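Deinococcus metallilatus belongs to a bacterial genus known for its tolerance of radiation and drying. Strain MA1002 was obtained from the air-conditioning system of a car. Transcripts of the wild type and of UV mutant No. 6, a derivative made by UV mutagenesis, were counted by RNA sequencing, with 1 library each. The trait for which the mutant was picked is not stated in the labels. The libraries held 30493865 reads for the wild type and 18432802 for the mutant, a depth ratio of 1.65, on 4203 genes of 3 contigs. There are no replicates, so the differences have no replicate check and no test was made. Intervals of single genes and of read counts or shares are 95% counting intervals only. Those of medians over genes come from the ranked ratios of these genes and also leave out variation between cultures.

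The most abundant transcripts were largely shared by both strains. DSPMA1002_00866, a hypothetical protein of contig 2 (94174 to 97446), took 6.52% of the wild type reads and 9.02% of the mutant reads, a log2 ratio of 0.47 (0.46 to 0.47). DSPMA1002_01536, an amidase-like protein with an S-layer homology domain, the kind of domain that anchors surface proteins to the cell wall, took 4.88% and 5.31%. DSPMA1002_01933, also with such a domain, took 3.32% and 2.40%. Of the 10 most abundant genes of each library, 8 were in both sets. They included the chaperonin GroEL (DSPMA1002_01410, log2 ratio 0.18), the chaperone DnaK (DSPMA1002_03793, -0.24), the translation factor EF-Tu (DSPMA1002_03203, 0.70) and the hypothetical protein DSPMA1002_01652 (-0.91). Those in the mutant set alone were cytochrome c oxidase subunit I (DSPMA1002_01630, 0.82), part of the terminal oxidase of respiration, and the A subunit of a V/A-type ATPase (DSPMA1002_03752, 0.71). Those in the wild type set alone were the uncharacterized proteins DSPMA1002_02294 (-1.27) and DSPMA1002_01343 (-0.42). The 10 most abundant genes took 25.8% of the wild type reads and 26.5% of the mutant reads. The exact 95% intervals (Clopper-Pearson) of these shares and of the contig shares below had half-widths of at most 0.0201 percentage points.

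Across the genome the mutant library differed from the wild type library in a way that followed position. On contig 1, a block of 239 neighbouring genes had almost no mutant reads, while most other genes of that contig were about 2-fold higher in the mutant library. Contigs 2 and 3 kept most genes within 2-fold. In total, 444 of 4092 genes were higher in the mutant library by 2-fold or more and 493 were lower. Higher genes thus made up 47.4% of the calls with TMM scaling. With upper quartile scaling, which shifts all genes by 0.20 on the log2 scale, the counts were 573 and 404, or 58.7% higher. Contig 1 alone held 345 of the higher and 248 of the lower genes, and without it the counts were 99 and 245. The share of reads on contig 1 was 8.23% in the wild type library and 11.2% in the mutant library.

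**Figure D1:**
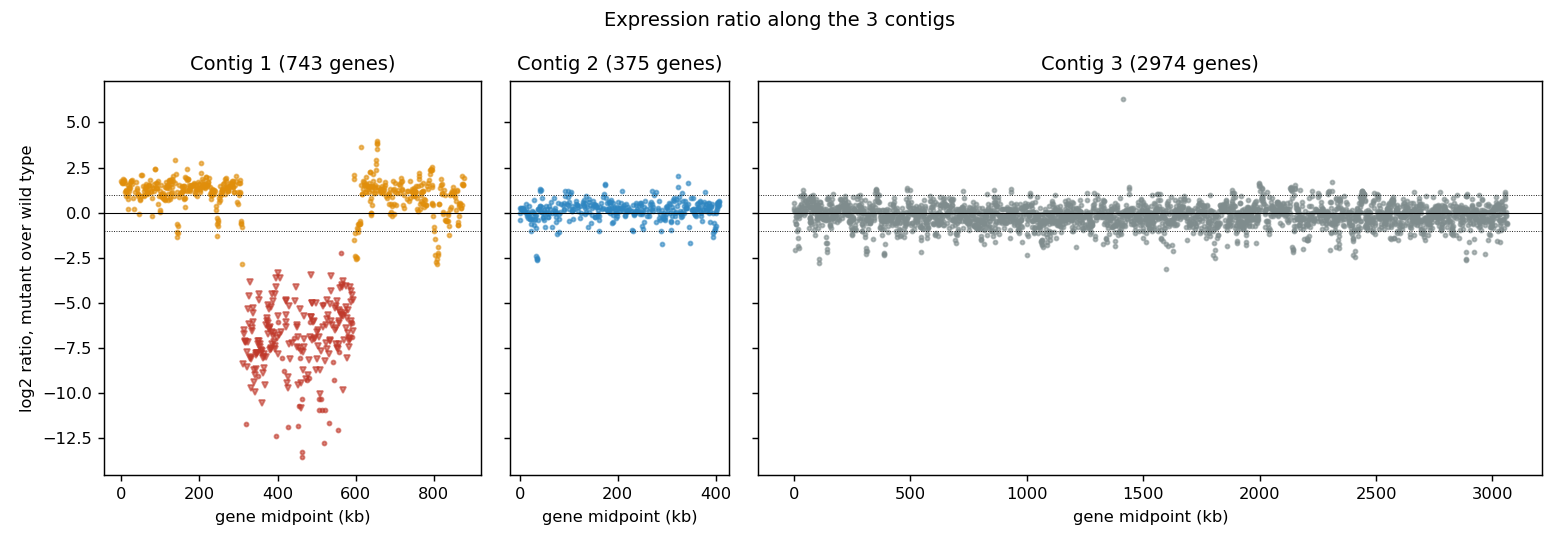
Log2 ratio of each gene past the 50-read minimum (mutant over wild type, TMM-scaled counts) against its midpoint in kb on contigs 1, 2 and 3, each drawn on its own length scale. Triangles mark genes with 0 mutant reads, drawn at their bound, and dotted lines mark 2-fold. The 226 red genes of the block all lie below the lower dotted line, while the other genes of contig 1 (orange) have a median of 1.22.

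The depleted block ran from DSPMA1002_00286 to DSPMA1002_00524, at 310781 to 594164 of contig 1, a length of 283 kb or 32.3% of the annotated span of the contig. Its genes together had 669343 reads in the wild type library and 412 in the mutant library. There were 0 mutant reads in 207 of its genes, 1 to 3 in 26 and more than 3 in 6. No gene outside the block had 0 mutant reads. All 226 block genes with at least 50 wild type reads were called lower, and 217 of them lay under 1/16 of their wild type level, against 0 of 3845 genes outside the block. A ratio under 1/16 was part of the rule that defined the block, so the count of 217 follows largely from that rule. The block holds 144 genes on the plus strand and 95 on the minus strand, with 67 changes of strand along it. Its median gene had 508 reads in the wild type library and 0 in the mutant library.

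Many kinds of genes lay in the block. The most abundant in the wild type library was the hypothetical protein DSPMA1002_00410, chosen after its values were seen, with 119085 wild type and 55 mutant reads. DSPMA1002_00454, annotated as the secreted serine protease Vpr of the subtilisin family, had 114993 and 10 reads, which is 6950-fold lower (3779 to 14493). The neighbours DSPMA1002_00411 (hypothetical) and DSPMA1002_00409 (a TatD-type DNase) had 39459 and 32641 wild type reads and 2 mutant reads each. Alpha-galactosidase (DSPMA1002_00364), which releases galactose from sugars, had 17628 and 2 reads. A histidine kinase (DSPMA1002_00463) had 10694 and 2. The ABC transporter peptide-binding protein DSPMA1002_00329 had 7420 and 0, at least 1495-fold lower. A gene annotated as the sigma factor SigA (DSPMA1002_00358), a class of protein that directs RNA polymerase to promoters, had 935 and 0, at least 188-fold lower. All 15 of the smallest log2 ratios lay in the block.

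The 4 longest runs of lower genes were also in the block, all on the plus strand. The longest, of 21 genes from DSPMA1002_00300 to DSPMA1002_00320 (329270 to 351312), held branched-chain amino acid transport permeases, penicillin-binding protein 1C and 4 genes for making dTDP-rhamnose, a sugar of cell surface polymers. A run of 11 genes from DSPMA1002_00335 to DSPMA1002_00345 held beta-glucuronidase, mannonate dehydratase and other genes for the use of uronic acids. A run of 10 from DSPMA1002_00474 to DSPMA1002_00483 held anthranilate-CoA ligase and anthraniloyl-CoA monooxygenase, enzymes that break down anthranilate. A run of 8 from DSPMA1002_00442 to DSPMA1002_00449 held a molybdate-binding protein, a molybdate-transporting ATPase and molybdopterin molybdotransferase, which serve the molybdenum cofactor. The median log2 ratios of the 4 runs, with genes at 0 set to their bound, were -7.90, -6.24, -6.89 and -9.39.

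The genes on either side of the block, chosen after their values were seen, had intermediate ratios. DSPMA1002_00285, a molybdenum-binding subunit of xanthine dehydrogenase just before the block, had 54246 wild type and 4616 mutant reads, a log2 ratio of -2.83 (-2.87 to -2.78). The preceding genes of the same strand, DSPMA1002_00281 to DSPMA1002_00284, had log2 ratios from -0.82 to -0.47. On the far side DSPMA1002_00525, a hypothetical protein, had 309 and 64 reads (-1.54, -1.96 to -1.15).

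**Figure D2:**
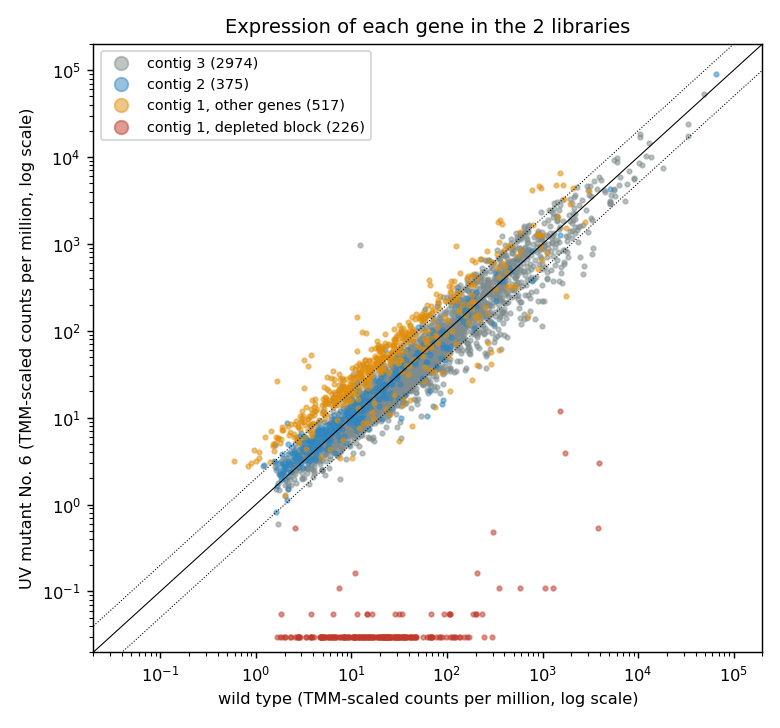
TMM-scaled read counts, relative to library size, of each gene past the 50-read minimum in the wild type library (x axis) and in the mutant library (y axis), both on log scales. The solid line marks equality and dotted lines mark 2-fold, and genes with 0 mutant reads are drawn at a fixed height near the bottom. The 226 block genes lie far below the line, and the gene of contig 3 far above it is DSPMA1002_02601, with 371 wild type and 17693 mutant reads.

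The rest of contig 1 was mostly higher in the mutant library. Of its 517 genes past the minimum, 345 were called higher and 22 lower, with a median log2 ratio of 1.22 (quartiles 0.81 and 1.54), or 2.32-fold. The median was 1.19 for genes of the plus strand and 1.25 for those of the minus strand. For comparison, contig 2 had a median of 0.17, with 18 genes higher and 15 lower of 375, and contig 3 a median of -0.14, with 81 higher and 230 lower of 2974. In windows of 50 kb with at least 20 genes, the medians ranged from -0.57 to 0.26 on contig 3 and from 0.02 to 0.36 on contig 2. The last window of contig 2, with 13 genes, had a median of 0.45. Of the 12 windows of contig 1 clear of the block, 10 had medians from 1.06 to 1.41, while the window from 800001 to 850000 (39 genes) had 0.03 and the last window (25 genes) had 0.65.

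The 4 longest runs of higher genes all lay in this part of contig 1, on the minus strand. Most genes of this part were called higher, and it held 47 runs of higher genes with 264 genes in all. The runs that start at DSPMA1002_00167, DSPMA1002_00591 and DSPMA1002_00554 had median log2 ratios of 1.49, 1.26 and 1.49. These lie inside the quartiles of all genes of this part (0.81 and 1.54), so these runs do not stand out from it. One run of 12 genes, DSPMA1002_00167 to DSPMA1002_00178, held L-fucose isomerase, a kinase annotated for xylulose or gluconate and several sugar transport genes, with log2 ratios from 1.06 to 1.67. Another of 12, DSPMA1002_00591 to DSPMA1002_00602, held inositol 2-dehydrogenase, myo-inosose-2 dehydratase and other genes for breaking down myo-inositol (1.08 to 1.69). A run of 11 genes, DSPMA1002_00554 to DSPMA1002_00564, included 5-oxoprolinase and the ferrous iron permease EfeU (1.17 to 2.28). The other run of 11, DSPMA1002_00579 to DSPMA1002_00589, was made of hypothetical proteins and a serine/threonine protein kinase. It reached further than the contig median, up to 3.97 (3.55 to 4.42) in DSPMA1002_00584, which had 51 and 483 reads.

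Of the 15 largest log2 ratios, 14 were on contig 1. Besides genes of the run just described they included DSPMA1002_00542, an uncharacterized membrane protein (353 and 2626 reads, log2 ratio 3.62, 3.46 to 3.79), and DSPMA1002_00129, annotated as beta-glucosidase or beta-mannosidase (3829 and 17428 reads, 7.53-fold, 7.27 to 7.80). CRISPR-associated genes, which make up a bacterial defence against foreign DNA, were among them too. Cas7 (DSPMA1002_00694) had 23875 and 76049 reads (5.27-fold, 5.19 to 5.35), and the adjoining DSPMA1002_00696 and DSPMA1002_00697 had log2 ratios of 2.39 and 2.55.

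The largest log2 ratio of all belonged to a gene of contig 3. DSPMA1002_02601, a hypothetical protein at 1411029 to 1413908 on the minus strand, had 371 wild type and 17693 mutant reads, which is 78.9-fold higher in the mutant library (71.2 to 87.7). Its neighbours, chosen after their values were seen, did not share this. DSPMA1002_02600 (N-acyl homoserine lactone hydrolase) had a log2 ratio of 0.04 and DSPMA1002_02602 (3-isopropylmalate dehydratase, large subunit) one of -0.24.

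Ribosomal protein genes were higher as a group in the mutant library. All 53 ribosomal protein genes lie outside contig 1, 20 of them were called higher and 0 lower, and their median log2 ratio of 0.93 (0.80 to 1.03) was at percentile 100 of matched random lists. The 53 genes were all above the median of contig 3. Their median lies just under 2-fold, so the count of called genes depends on the scaling. Upper quartile scaling, which raises every ratio by 0.20, would call more of them. Ribosomal protein L10 (DSPMA1002_03210) had 16028 and 24773 reads (1.35) and L7/L12 (DSPMA1002_03211) 19671 and 29313 (1.30), while L21 (DSPMA1002_01421) was at 0.12 and L32 (DSPMA1002_01212) at 0.22. The 4 RNA polymerase core subunits were between 0.48 and 0.86, with 0 called. Of the 27 aminoacyl-tRNA synthetases, which load transfer RNAs, 1 was higher and 3 were lower. Of the 25 outside contig 1, 0 were higher and 2 lower, and their median was at percentile 49.3. The cysteinyl-tRNA synthetase (DSPMA1002_03462) was 4.28-fold lower (4.21 to 4.36). The tyrosyl-tRNA synthetase (DSPMA1002_01195), chosen after its value was seen, was 4.15-fold lower. Ribosomal protein and stress defence genes are known to follow growth stage. The labels place both cultures in the exponential phase at 24 h, and their cell densities are not given in the sources used here.

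Because contig 1 moves any list with members on it, list medians are given for the genes outside contig 1 unless stated, a restriction chosen after the data were examined. The respiratory chain and ATP synthase list had 27 such genes, with 0 called and a median of 0.31 at percentile 99.97. Many of them are neighbours, such as the NADH-quinone oxidoreductase subunits DSPMA1002_03004 to DSPMA1002_03017, which random lists do not imitate. The same limit holds for the ribosomal protein genes. Amino acid degradation had 4 of 20 genes higher and 0 lower, with a median of 0.62 at percentile 100. The phage and CRISPR list had 4 of 8 genes higher and 0 lower, with a median of 0.97 at percentile 100, and those 4 belong to a Cascade-type CRISPR locus of contig 3. With contig 1 included the median of this list was 1.35, and it was 0.39 when the whole annotation text was searched, an alternative chosen after the data were examined. Amino acid and peptide transport had 1 of 26 higher and a median of 0.13 at percentile 97.7. For the planned lists with contig 1 included, these 4 percentiles were 99.7, 100, 100 and 85.2. With contig 1 included, fatty acid degradation (99.1), sugar transport (97.8), the pentose phosphate pathway (1.29) and transposases (0) also lay outside the central 95% of random lists, and none of these did outside contig 1.

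The oxidative stress list was the only list with a low percentile outside contig 1. Of its 32 genes there, 8 were lower and 0 higher, with a median of -0.41 at percentile 0.49 (0.48 with contig 1). The lowest, DSPMA1002_02257 (-1.76), matched through its link to thioredoxin and is phosphoadenosine phosphosulfate reductase, an enzyme of sulfate assimilation. The other 7, chosen after their values were seen, ranged from a starvation protein Dps (DSPMA1002_01061, -1.73), which binds DNA and iron, to the peroxiredoxin OsmC (DSPMA1002_03385, -1.31). They included a Cu-Zn superoxide dismutase (DSPMA1002_03557, -1.48), which removes superoxide. More abundant genes of the same kinds, also chosen after their values were seen, were not called. An Fe-Mn superoxide dismutase (DSPMA1002_02455, 245227 wild type reads) was at -0.21 and another Dps (DSPMA1002_03855, 28059 wild type reads) at -0.64. A peroxidase (DSPMA1002_00903) was at 0.70.

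**Figure D3:**
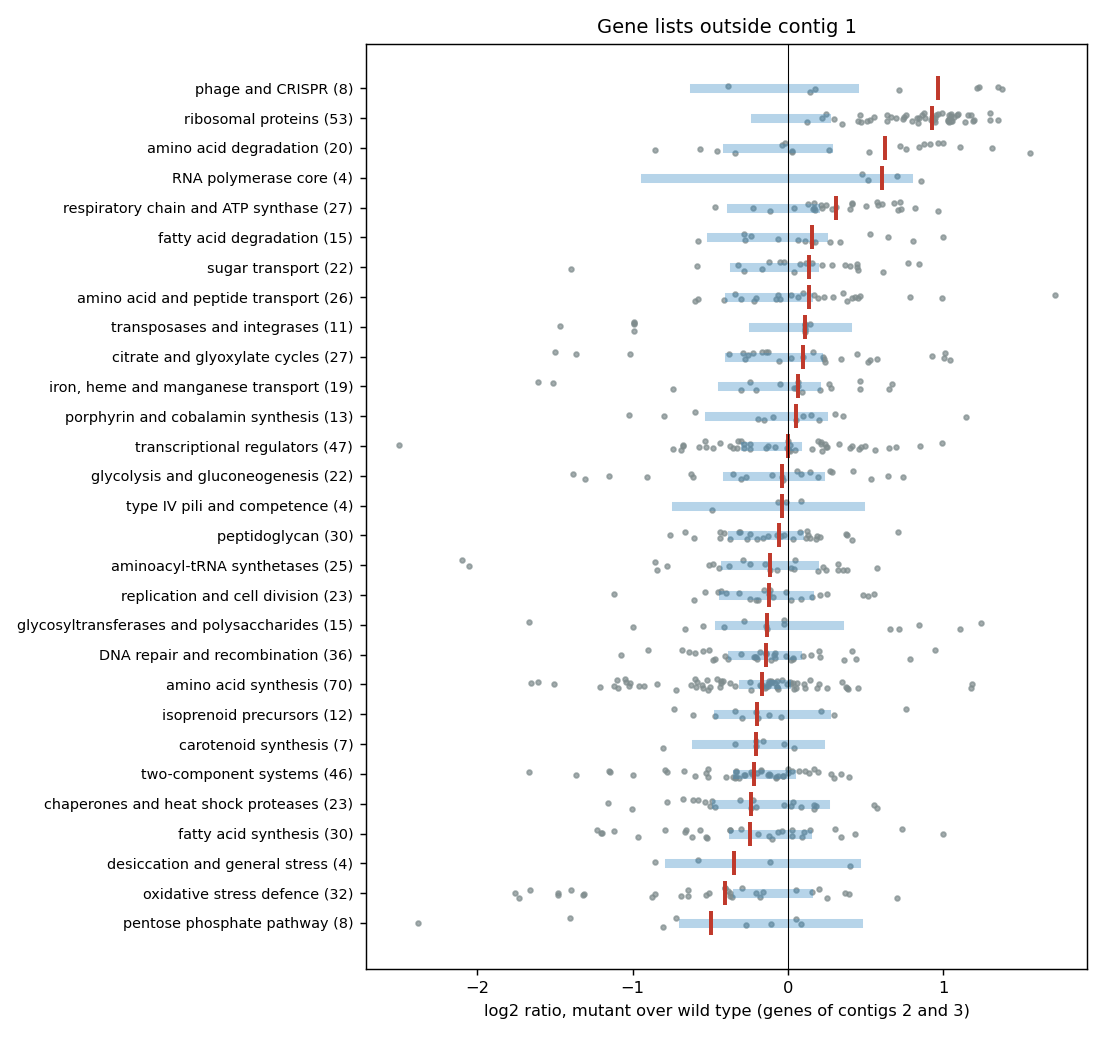
Log2 ratio (mutant over wild type) of the measured genes of each list outside contig 1, with the number of genes in brackets. Grey points are genes, red marks are list medians, and blue bars span the central 95% of the medians of 10000 random lists matched on expression. The ribosomal protein median of 0.93 and the oxidative stress median of -0.41 lie beyond their bars.

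Carotenoid synthesis, which makes the red pigment typical of the genus, held no called gene. Its 7 members had a median of -0.20 at percentile 42.8. Phytoene synthase (DSPMA1002_03388), the first dedicated enzyme of the pathway, had 671 and 232 reads (-0.81, -1.03 to -0.59), and its neighbour phytoene desaturase (DSPMA1002_03387) was at -0.34. The 3 genes annotated as lycopene beta-cyclase were at -0.21 (DSPMA1002_03804, annotated as glutamate racemase too), -0.20 (DSPMA1002_01368) and 0.04 (DSPMA1002_02195). Geranylgeranyl diphosphate synthase (DSPMA1002_01903) was at -0.16 and a further phytoene desaturase (DSPMA1002_01371) at -0.02. The 12 isoprenoid precursor genes held no called gene either.

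DNA repair and recombination had 1 of 36 genes lower, a TDG/mug-type DNA glycosylase (DSPMA1002_03466, -1.08), and 0 higher. A single-stranded DNA-binding protein (DSPMA1002_04079) was at 0.95 and DNA gyrase subunit A (DSPMA1002_02587) at 0.78. The former lies between the ribosomal protein genes S6 (DSPMA1002_04078, 0.92) and S18 (DSPMA1002_04080, 1.03). A single-stranded DNA-binding protein of contig 2 (DSPMA1002_00883) was at 0.21. These 3 further genes were chosen after their values were seen. Chaperones and heat shock proteases outside contig 1 had 2 of 23 genes lower, ClpP (DSPMA1002_03895, -1.16) and ClpX (DSPMA1002_03896, -1.01), which together form a protease. In replication and cell division the 1 lower gene of 23 was annotated as an esterase (DSPMA1002_03791, -1.12), a function outside the name of the list.

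In central metabolism, the citrate and glyoxylate list had 3 higher and 3 lower of 27 genes. A gene annotated as the E2 component of 2-oxoglutarate dehydrogenase (DSPMA1002_04256) was at 1.04 and succinyl-CoA synthetase subunit beta (DSPMA1002_02752) at 1.01. The other genes with that E2 annotation, chosen after their values were seen, were not called. They were at 0.53 (DSPMA1002_01358), -0.06 (DSPMA1002_03649) and -0.28 (DSPMA1002_03563). None of the 3 lower genes, chosen after their values were seen, is an enzyme of these cycles proper. They are 2-isopropylmalate synthase (DSPMA1002_02160, -1.02), an enzyme of leucine synthesis, and a pair annotated as decarboxylating malate dehydrogenases (DSPMA1002_03898, -1.36, and DSPMA1002_03901, -1.496). Glycolysis had 0 higher and 3 lower of 22, among them glucose-6-phosphate isomerase (DSPMA1002_02324, -1.39), and a median of -0.035 at percentile 59.3. Another of the lower genes, phosphoenolpyruvate carboxylase (DSPMA1002_02650, -1.15, chosen after its value was seen), is outside the name of the list. The pentose phosphate list had 2 lower of 8, among them a ribulose-phosphate 3-epimerase of contig 2 (DSPMA1002_00808, -2.38), and a median of -0.50 at percentile 8.68. Another ribulose-phosphate 3-epimerase, of contig 3 (DSPMA1002_02218), was at 0.05. Fatty acid synthesis had 1 higher and 4 lower of 30, and the higher one is methylmalonyl-CoA mutase (DSPMA1002_02497, 1.001), also chosen after its value was seen, which is outside the name of that list and is counted in amino acid degradation too. Fatty acid degradation had 1 higher of 15, and amino acid synthesis 2 higher and 11 lower of 70, among the latter 2-isopropylmalate synthase again and an endopeptidase (DSPMA1002_02346, -1.09, chosen after its value was seen) outside the name of the list. Porphyrin and cobalamin synthesis had 1 higher and 1 lower of 13. Iron, heme and manganese transport had 2 lower of 19, both annotated for manganese uptake, MntA (DSPMA1002_02253, -1.61) and MntB (DSPMA1002_03374, -1.51). The MntA gene belongs to a run of lower genes, described below, that also holds enzymes of sulfate assimilation.

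Among the remaining lists, sugar transport had 1 lower of 22 genes, two-component systems 4 lower of 46, transcriptional regulators 1 lower of 47, and glycosyltransferases and polysaccharides 2 higher and 1 lower of 15, the lower one being a histidine kinase (DSPMA1002_01890, -1.67, chosen after its value was seen) that is counted in two-component systems too. No gene was called in peptidoglycan synthesis (30 genes), type IV pili and competence (4) or desiccation and general stress (4). Transposases and integrases had 1 lower of 11, while 9 of the 10 lower genes of the whole list of 22 lay in the block. No product name matched the surface layer list. In the whole annotation text, an alternative chosen after the data were examined, it matched 12 genes, of which 0 were higher and 2 lower, both in the block. Of 29 lists with a value outside contig 1, the 23 within the central 95% of random lists had percentiles that ranged from 8.68 to 95.7.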

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

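TMM scaling from contig 3 alone, counts without contig 1 and the search of the whole annotation text were chosen after seeing the data. No paired analysis was possible because there is 1 library per group, and for the same reason no library could be left out. Of 28 values for the counts of higher and lower genes, 22 stayed within 1.5 times the main counts. Those that did not were 35 higher and 271 lower genes at 4-fold, 731 and 911 at 1.5-fold, and 99 and 245 without contig 1, as those thresholds and that gene set dictate. Upper quartile scaling shifted all genes by 0.20 and contig 3 scaling by 0.13, so splits of higher against lower moved with them (573 to 404 and 527 to 430). With upper quartile scaling the list medians, as log2 ratios with contig 1 included, moved to 0.062 for DNA repair, -0.20 for oxidative stress, 1.14 for ribosomal proteins, 0.61 for the respiratory chain, 0.049 for amino acid synthesis, 0.16 for peptidoglycan, -0.32 for desiccation and general stress, -0.011 for two-component systems and 0.81 for RNA polymerase. With contig 3 scaling they moved to -0.27 for oxidative stress, 1.06 for ribosomal proteins and -0.022 for amino acid synthesis. Each of these moves equals the shift of all genes, because 1 factor applies to every gene. In 11 lists the median changed sign under upper quartile or contig 3 scaling, so no direction is given for these. The whole annotation text gave 0.39 for phage and CRISPR and -0.32 for desiccation and general stress, from other sets of genes. Without contig 1 the transposase list reversed, from -0.99 to 0.11, because 9 of its genes lie in the depleted block. Of the 290 list values in all, 275 stayed within the 95% interval of the main median (within 0.2 for the lists of fewer than 6 genes, which have no interval) and 14 moved. The 1 other value is the transposase median, the only sign change in a list beyond the central 95% of random lists with contig 1 included. Amino acid and peptide transport, beyond it only outside contig 1, changed sign with contig 1 included, from 0.043 to -0.017 at a minimum of 10 reads and to -0.11 with the whole annotation text, both within its interval. Of the 14 that moved, 3 changed sign in lists within the central 95%, DNA repair, amino acid synthesis and peptidoglycan under upper quartile scaling. For 231 named genes, 1331 of 1617 values stayed within their counting interval and 286 moved. No gene called at 2-fold changed sign, while 5 values of 3 uncalled genes did, 3 of them beyond the counting interval. These were DSPMA1002_01371 (-0.024 to 0.18 with upper quartile scaling) and DSPMA1002_02715 (-0.12 to 0.089 with upper quartile and to 0.018 with contig 3 scaling). The calls by the whole counting interval numbered 347 higher and 425 lower. Depth limits what the block can show, since 10 of its 226 genes with at least 50 wild type reads had too few wild type reads for a floor of 3 mutant reads to lie under 1/16.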

Other observations

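The runs and genes in this paragraph and the next were chosen after their values were seen. A run of 7 genes of contig 3, DSPMA1002_02253 to DSPMA1002_02259 (1062582 to 1069323), was lower in the mutant library and held, besides an MntA-type ATPase, an ABC transporter permease and a hypothetical protein, sulfate adenylyltransferase, adenylylsulfate kinase, phosphoadenosine phosphosulfate reductase and sulfite reductase, the enzymes that turn sulfate into sulfide. Log2 ratios in it ranged from -1.90 to -1.51, and sulfite reductase (DSPMA1002_02259) had 103037 wild type and 16633 mutant reads. A run of 4 genes annotated for riboflavin synthesis, DSPMA1002_01508 to DSPMA1002_01511, ranged from -2.29 to -1.97. On contig 1, where most genes were higher, 2 neighbouring runs went the other way. DSPMA1002_00706 to DSPMA1002_00708 and DSPMA1002_00709 to DSPMA1002_00714 hold allantoate deiminase, ureidoglycine aminohydrolase, tartronate-semialdehyde synthase and malate synthase, annotated for the use of purine breakdown products and glyoxylate. Allantoate deiminase (DSPMA1002_00710) had 8882 and 756 reads (7.10-fold lower, 6.59 to 7.66). DSPMA1002_00528 to DSPMA1002_00532 ranged from -2.56 to -1.12. They are annotated as a transcriptional regulator, a glutathione-binding protein, dipeptide and peptide transport permeases and gamma-glutamyltranspeptidase. This run starts at 597322, close to the end of the depleted block at 594164. Whether its lower level is tied to the edge of the block was not tested.

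Other runs outside contig 1 were higher in the mutant library. Besides ribosomal protein genes, they included a Cascade-type CRISPR locus (DSPMA1002_03309 to DSPMA1002_03315, 7 genes, 1.22 to 1.43). Another held the phosphate uptake genes pstB, pstA and pstC with a phosphate-binding protein and an uncharacterized protein (DSPMA1002_03192 to DSPMA1002_03196, 5 genes, 1.21 to 1.64). A run of glycosyltransferases and a hypothetical protein (DSPMA1002_01550 to DSPMA1002_01554, 5 genes) ranged from 1.08 to 1.29. Proline dehydrogenase and 1-pyrroline-5-carboxylate dehydrogenase, which break down proline, formed a run with an NAD(P)H dehydrogenase (DSPMA1002_03328 to DSPMA1002_03330, 3 genes, 1.31 to 1.56). The CRISPR locus of contig 1 (DSPMA1002_00688 to DSPMA1002_00697) ranged from 1.28 to 2.55. In all, 10 runs of higher and 14 runs of lower genes were found outside contig 1, not all of which are named here. The lowest single gene there was DSPMA1002_02785, a hypothetical protein of contig 3 with 30274 and 2070 reads (8.84-fold lower, 8.45 to 9.25).

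All tests of explanations in the paragraphs that follow, with their limits, were chosen after the results were seen. For the block of contig 1, lower depth of the mutant library, which acts on every gene, is argued against by the 1269 genes outside the block with 50 to 508 wild type reads, of which 0% (upper limit 0.29%) had 0 mutant reads, against 90.7% of the 107 such genes in the block. Loss of the block's DNA stays open as a hypothesis that these values neither establish nor exclude. The 22 block genes that did not themselves meet the rule that defined the block (at least 50 wild type reads and a ratio under 1/16) had 10 mutant reads. That is 1.98% (0.95% to 3.66%) of the number that the read ratio of contig 3 predicts, against 0.109% (upper limit 0.12%) for the whole block. This comparison cannot decide. Genes picked for few wild type reads or a ratio not under 1/16 can have a higher share through that selection itself. Silencing of an intact block cannot be told apart from loss of its DNA, because DNA was not measured and only 6 block genes had more than 3 mutant reads. Those 6 genes held 377 of the 412 mutant reads, and among the 6 genes with at least 30000 wild type reads the mutant reads ranged from 0.00507% to 0.481% of the wild type reads, a 94.9-fold spread whose source was not tested. Sequencing the mutant's genome would decide.

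For the higher level of the other contig 1 genes, the scaling between the libraries is argued against by the difference of their median from that of contig 3, which is 1.35 on the log2 scale and which no single factor alters. More genomic DNA in the mutant library, which would raise weakly expressed genes of every contig, is argued against as the whole cause by the 335 genes outside contig 1 with the fewest wild type reads per kb, whose median was 0.26 (0.22 to 0.33). A higher copy number of the rest of contig 1 stays open as a hypothesis that these values neither establish nor exclude, because DNA was not measured. The shift was not uniform, as 1 of the 12 windows of 50 kb clear of the block had a median of 0.027, below the upper quartile of contig 3 (0.19), while 10 had medians from 1.06 to 1.41. After matching on wild type reads per kb, the difference from genes outside contig 1 was 1.01 for the 171 more strongly expressed genes and 1.32 for the other 346.

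For the higher level of DSPMA1002_02601, a constant share of reads taken from another counted gene is argued against, since a share cannot exceed its donor's ratio. The highest log2 ratio of any other gene past the read minimum was 3.97, below the lower limit of 6.15. Donors among stable RNAs, which held no reads, or outside the coding rows could not be examined. Read-through from a neighbouring gene that itself rose is argued against by the neighbours, the higher of which had a log2 ratio of 0.036. Read-through present in the mutant alone, from a neighbour of unchanged level, was not tested. A difference of this gene between the strains stays open and untested, and reads that match copies in the mutant genome alone could not be examined without its sequence.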
